A study of Mus musculus with 20 samples.

How the data were processed

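RNA was measured in splenic B cells of male C57BL/6 mice on 20 Affymetrix mouse genome arrays, 1 hybridization per array, in 5 groups of 4. Per the labels' protocols, CD19-positive B cells were isolated from spleen by magnetic sorting with beads against CD43, CD11c, CD11b, DX5 and CD90, to a purity above 99%, and were cultured in medium with 10% fetal calf serum. LPS was used at 1 µg/ml and the anti-CD40 antibody FGK45 at 10 µg/ml, for 24 h or 72 h. Per the same protocols, 100 ng of total RNA was amplified and labelled, and 15 µg of cRNA was hybridized for 16 h. Groups and replicate numbers were read from the sample titles. The labels do not say whether a replicate was a separate mouse, pool or culture.

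The deposited table holds 45101 probe sets as linear intensities. The submitters' processing notes name GCOS, GCRMA, affy and limma without versions or roles. The mean intensity after trimming the lowest and highest 2% of probe sets was 100 on every array of the deposited table, which is the scaling of GCOS signals, and the values were not on a log scale. Array medians differed 2.99-fold, from 11.5 to 34.5, and 32.2% to 56.2% of the values of an array lay below the pseudocount of 16. No detection calls and no depth are given in the sources used here, and the number of arrays limits the precision of each value.

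A rule fixed before the data were examined set log2(value + 16) and, for medians differing more than 1.2-fold, quantile normalization across the 20 arrays. Of the probe sets, 34958 carried exactly 1 gene symbol, 932 several and 9211 none, and those with several or none were left out. The symbols of 34754 probe sets matched 1 gene of the reference table, and 0 symbols needed an update. For each of 18194 genes the probe set with the highest mean over all arrays was used. The 12346 genes with at least 4 arrays above the 50th percentile of all values (5.19 on the log2 scale) were tested, and 7420 of them had more than 1 probe set. Aicda, Ighg1 and Ighd had no probe set with a single symbol and were not analysed here.

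Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit on the 5 group means, contrasts.fit, eBayes with an intensity trend), two-sided, at a Benjamini-Hochberg adjusted p of 0.05 within each of 8 pairwise comparisons and the interaction of anti-CD40 with time. Genes with an absolute log2 difference of at least 1 were also counted. Folds are on the scale of intensity + 16, and none is given for a gene whose mean in either group lay under 5.19, where the pseudocount sets much of the size. Python 3.11.15 and matplotlib 3.10.9 served for tables and figures.

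A total of 32 gene lists, 24 of pathways and 8 of cell types, was fixed at the same stage. Each was tested against all other genes with camera of limma at a preset correlation of 0.01, adjusted over the 32 lists of a comparison. The same test was run with the correlation estimated per list, and with fry, which asks whether the genes of a list move one way on balance without comparing them with other genes. Members were counted as higher, lower or not past the test after adjustment over all genes tested, and again adjusted over the list alone. Agreement of a pair of comparisons that share no array was described by Pearson and Spearman correlations across genes.

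Genes were named by a rule fixed in advance. For the comparisons of LPS with naive cells and of LPS plus anti-CD40 with LPS, these were the 8 largest rises and 8 largest falls among genes past the test whose arrays did not overlap, and for the other comparisons the 4 and 4. Within each list up to 4 members past the test with the largest difference could be named, and 1 that moved against them. A fixed panel of B cell and plasma cell genes was added. The rule passed over 1 gene without a gene name in the comparison of LPS plus anti-CD40 at 24 h with naive cells. Of those candidates the text names mainly genes whose call held under every alternative with all groups at full size. For 500 pairs of a named gene and a comparison the gene had other probe sets, which passed the test the same way in 341 and the opposite way in 2 (Nfkbiz and H2-D1, both for LPS at 24 h against naive cells).

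Whether replicate numbers pair the samples was checked on deviations from the group means. Arrays with the same number in different groups correlated with a median of 0.22 over 16 pairs (0.08 to 0.5), against -0.03 for other numbers, and 11 of 15 arrays were best correlated with an array of their own number. Numbers 6A, 44 and 45 were treated as separate from 6, 4 and 5, since the labels do not relate them, although in LPS plus anti-CD40 the 24 h array 6 correlated with 6A at 0.33, and array 4 with 44 at 0.25 and with 45 at 0.33. The count and the block by number would differ if they were the same. In the comparisons of LPS at 24 h and at 72 h with naive cells all 3 shared numbers correlated above 0.1, and the fit with the number as a block gave 4858 and 2568 genes, against 4293 and 2959 without it. Pairs of arrays with different numbers were also more alike within a number set (6, 7 and 6A, or the other numbers) than between the sets (median 0.07 over 66 pairs, against -0.12 over 78), which was treated as a possible batch, although the labels give no dates.

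The alternatives were no filter and a filter at the 70th percentile, pseudocounts of 1 and 64, the values as deposited without quantile normalization, arrays centred on their medians, all probe sets, the mean of a gene's probe sets, only the groups compared, array weights, robust variance shrinkage, replicate number as a block (fixed, or random with statmod 1.5.0), an adjusted p of 0.01, estimated correlation and fry for lists, and each array left out in turn. Number sets as a block, comparisons within each set and, for the lists, arrays centred on their medians were added after the data were seen. The test was tried on simulated data built for the comparison of LPS plus anti-CD40 with LPS at 24 h, with 100 of 12346 genes changed at each of 2 sizes. It recovered 61% of 2-fold and 99% of 4-fold changes, called 8 unchanged genes, found the shifted list and called 0 other lists. Noise was drawn independently for each gene and array, without the correlation between genes or the likeness of same-numbered arrays. The simulation therefore cannot show how often lists are called falsely in the real data.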

Results

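Transcript levels were measured in splenic B cells of male C57BL/6 mice on 20 Affymetrix arrays, 4 in each of 5 groups. The labels give no culture time for the naive cells, which are taken here as uncultured. The other 4 groups were cultured for 24 h or 72 h with lipopolysaccharide (LPS, 1 µg/ml), which activates B cells through Toll-like receptor signalling, either alone or together with an agonistic antibody against the co-stimulatory receptor CD40 (10 µg/ml). No group was cultured without LPS, so differences from naive cells hold the effect of culture as well as that of the stimulus. The values were linear intensities whose trimmed mean was 100 on every array, while the array medians ran from 11.5 to 34.5. Levels are given as log2(intensity + 16) after quantile normalization, and differences as log2 ± SE with n = 4 per group. For a gene whose mean in either group lay under 5.19, called dim below, the pseudocount of 16 sets much of the size of the difference. The number of arrays limits the precision of every value. The p-values measure only the spread between these samples, which can be technical, since the labels do not say whether the replicates were separate mice or cultures. The first component of the 20 arrays held 38.1% of the variance, and naive arrays and 24 h arrays lay at its opposite ends. Deviations from the group means were more alike within the number sets (6, 7 and 6A, or the other numbers) than between them, so each comparison was also made within these number sets. Among arrays numbered 6, 7 or 6A, each group with LPS alone had only 1 array. Counts and p-values within that set thus rest on the spread of the other groups.

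**Figure D1:**
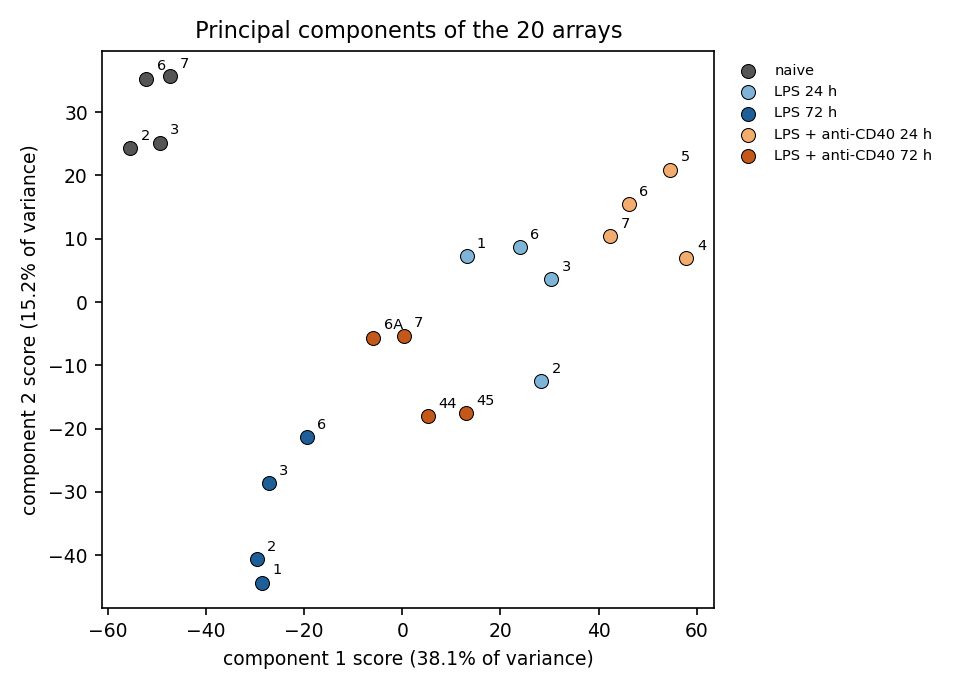
Principal components of the 20 arrays, with component 1 (38.1% of variance) on the x axis and component 2 (15.2%) on the y axis as unitless scores, 1 point per array coloured by group and marked with its replicate number. Naive arrays lie between -55.4 and -47.4 on component 1 and the 24 h arrays with LPS plus anti-CD40 between 42.4 and 57.9.

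The comparison of LPS at 24 h with naive cells asked which genes differed after a day of culture with LPS. Of 12346 genes tested 4293 changed, of which 2190 were higher and 2103 lower at 24 h, and 949 and 855 of these changed at least 2-fold. Zbtb32, a zinc finger repressor of activated lymphocytes, rose by 4.77 ± 0.21 (adjusted p = 1.8e-13) from a dim level in naive cells. Uhrf1, which maintains DNA methylation through replication, rose by 4.36 ± 0.32, the fatty acid carrier Fabp5 by 4.17 ± 0.21 and the interferon-induced RNA sensor Ifih1 by 3.42 ± 0.23. The cytokine genes Il6 and Il10 rose by 3.31 ± 0.29 and 2.84 ± 0.36, also from dim levels (4.18 and 4.88). Fos (-6.64 ± 0.62, adjusted p = 1.2e-08) and Klf4 (-3.95 ± 0.45) fell to dim levels, and Dusp1 was 17.6-fold lower (-4.14 ± 0.43). Centring each array on its median, in place of quantile normalization, moved the split to 1445 higher and 2113 lower. Within number sets, 2935 genes passed among the other arrays and 2854 among arrays numbered 6 or 7.

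At 24 h 28 of 29 mitosis genes rose, 28 also when adjusted over the list alone (median log2 difference 2.39, adjusted p = 6.5e-26), led by Bub1 (3.31 ± 0.25), a spindle checkpoint kinase, and Birc5 (3.17 ± 0.25). Of 30 DNA replication genes 28 rose, 28 adjusted over the list alone, with Cdc6, which licenses replication origins, at 3.61 ± 0.23 (list median 2.07, adjusted p = 1.9e-23). Of 34 genes of ribosome biogenesis and Myc targets 33 rose, 34 adjusted over the list alone, among them Srm at 2.27 ± 0.16 (median 1.27, adjusted p = 8.5e-18). Cholesterol synthesis rose in 19 of 20 genes, 19 adjusted over the list alone, with squalene epoxidase (Sqle) at 2.93 ± 0.23 (adjusted p = 1.4e-13). Amino acid transport and one-carbon genes rose in 17 of 22 and fell in 1, with the same counts adjusted over the list alone, and the transporter subunit Slc7a5 rose by 3.28 ± 0.28 (adjusted p = 8.7e-11). Glycolysis genes rose in 15 of 23 and fell in 3, with 16 and 3 adjusted over the list alone, Ldha rising by 2.24 ± 0.25, but the list's call (adjusted p = 1.2e-06) had adjusted p = 0.13 with an estimated correlation. Interferon response genes rose in 18 of 28, 20 adjusted over the list alone (adjusted p = 7.5e-07), with adjusted p = 0.16 with an estimated correlation.

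Most genes of the lists for the naive state, MHC class II, BCR signalling, marginal zone markers and B cell identity fell over the same 24 h. Of 24 genes of the naive state and lymphoid trafficking 21 fell, 22 adjusted over the list alone (median -1.55, adjusted p = 6.1e-15), including S1pr1, the receptor for egress from lymphoid tissue, at -2.96 ± 0.2. Of 16 genes of MHC class II presentation 12 fell, 12 adjusted over the list alone (median -1.09, adjusted p = 1.1e-08), with H2-Oa at -2.92 ± 0.23. Of 26 genes of B cell receptor (BCR) signalling 20 fell and 1 rose, with the same counts adjusted over the list alone (median -0.78, adjusted p = 1.3e-08), with the kinase gene Blk at -1.93 ± 0.23. Marginal zone B cell markers fell in 10 of 12 genes, 10 adjusted over the list alone (median -1.49, adjusted p = 1.1e-07), with Cd1d1 at -2.48 ± 0.18. B cell identity genes fell in 20 of 24, with 20 down and 1 up adjusted over the list alone (adjusted p = 3.1e-08), with Cr2 at -2.18 ± 0.18, and had adjusted p = 0.07 with an estimated correlation. The plasma cell programme was not past its list test (adjusted p = 0.81, 3 genes up, 1 down and 13 not past), although the plasma cell regulator Prdm1 rose by 1.73 ± 0.29 and the immunoglobulin joining chain Jchain was lower (-2 ± 0.5). Of the 32 lists 16 passed in this comparison, and 11 did with the correlation between genes estimated from the data.

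The comparison of LPS at 72 h with naive cells asked which genes differed after 3 days of culture with LPS. Here 2959 genes changed, 1486 higher and 1473 lower, 654 and 478 of them at least 2-fold. Tent5c, which encodes a poly(A) polymerase, rose 31.8-fold (4.99 ± 0.31, adjusted p = 6.8e-11). Il10 rose by 4.39 ± 0.36 and Bhlha15, a factor of secretory cells, by 3.83 ± 0.25, both from dim levels in naive cells (4.88 and 4.37), while Prdm1, which drives plasma cell differentiation, rose 18-fold (4.17 ± 0.29, adjusted p = 3e-10). Xbp1, the transcription factor of the secretory expansion, rose by 1.61 ± 0.17. Fos was lower than in naive cells (-4.95 ± 0.62, and -5.6 without LPS replicate 6) and the repressor gene Bcl6 was lower too (-1.22 ± 0.23). Centring on array medians moved all genes by a median of -0.14 and the split to 767 higher and 1911 lower. Within number sets, 1377 genes passed among the other arrays and 2125 among arrays numbered 6 or 7.

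Of 17 plasma cell programme genes 14 rose, 14 adjusted over the list alone (median 1.61, adjusted p = 6.5e-15), with Ell2 at 2.39 ± 0.26 and Edem1 at 2.32 ± 0.15. Of 37 genes of folding and secretion in the endoplasmic reticulum (ER) 32 rose, 33 adjusted over the list alone (median 1.12, adjusted p = 2.4e-22), with the coat protein Sec24d at 2.85 ± 0.23. Mitosis genes stayed above naive cells, 28 of 29 past the test and 28 adjusted over the list alone (median 1.88, adjusted p = 5.7e-29), with Mki67 at 2.4 ± 0.25. Interferon response genes rose in 25 of 28, 25 adjusted over the list alone (adjusted p = 1.5e-17), Isg20 rising by 2.87 ± 0.23. Marginal zone markers fell in 8 of 12 and rose in 1, with the same counts adjusted over the list alone (median -1.29, adjusted p = 7.2e-05). DNA replication genes rose in 17 of 30 and fell in 2, with 18 and 2 adjusted over the list alone (median 0.63, adjusted p = 3.5e-06), and had adjusted p = 0.16 with an estimated correlation. MHC class II genes fell in 6 of 16, 9 adjusted over the list alone (adjusted p = 0.00029), with adjusted p = 0.16 with an estimated correlation. Class switching genes were not past the list test (adjusted p = 0.21, 5 up and 19 not past, and 0.027 among arrays numbered 6 or 7) and neither were ribosome biogenesis genes (adjusted p = 0.66, 3 up, 5 down and 26 not past, median 0 and mean -0.06). In all 16 of 32 lists passed, and 6 with an estimated correlation.

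The change between 24 h and 72 h of LPS asked how the response moved on with time. Of the 3305 changed genes 1605 were higher and 1700 lower at 72 h, 588 and 613 at least 2-fold. Jchain rose 20.1-fold (4.33 ± 0.5, adjusted p = 8.3e-07), the light chain gene Igkv15-103 by 3.66 ± 0.38, the protease inhibitor Slpi by 3.52 ± 0.28 and Prdm1 by 2.44 ± 0.29. The rRNA processing gene Rrp9 fell (-2.92 ± 0.35), as did Fabp5 (-2.48 ± 0.21) and the replication helicase gene Mcm2 (-2.11 ± 0.15). The plasma cell programme rose in 13 of 17 genes, 14 adjusted over the list alone (median 1.73, adjusted p = 1.1e-13), and ER folding and secretion in 25 of 37, 26 adjusted over the list alone (median 0.68, adjusted p = 1e-11). DNA replication fell in 28 of 30 genes, 29 adjusted over the list alone (median -1.48, adjusted p = 3e-23), and ribosome biogenesis in 33 of 34, 34 adjusted over the list alone (median -1.26, adjusted p = 4.8e-25). Genes of the class switching list, tested without Aicda and with general DNA repair genes, fell in 16 of 24, with 16 down and 1 up adjusted over the list alone (adjusted p = 5.2e-05), among them the uracil glycosylase Ung at -1.89 ± 0.22. MHC class II genes rose in 10 of 16, with 11 up and 1 down adjusted over the list alone (median 0.74, adjusted p = 2e-05), and had adjusted p = 0.11 with an estimated correlation. Of the 32 lists 18 passed, and 7 with an estimated correlation.

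**Figure D2:**
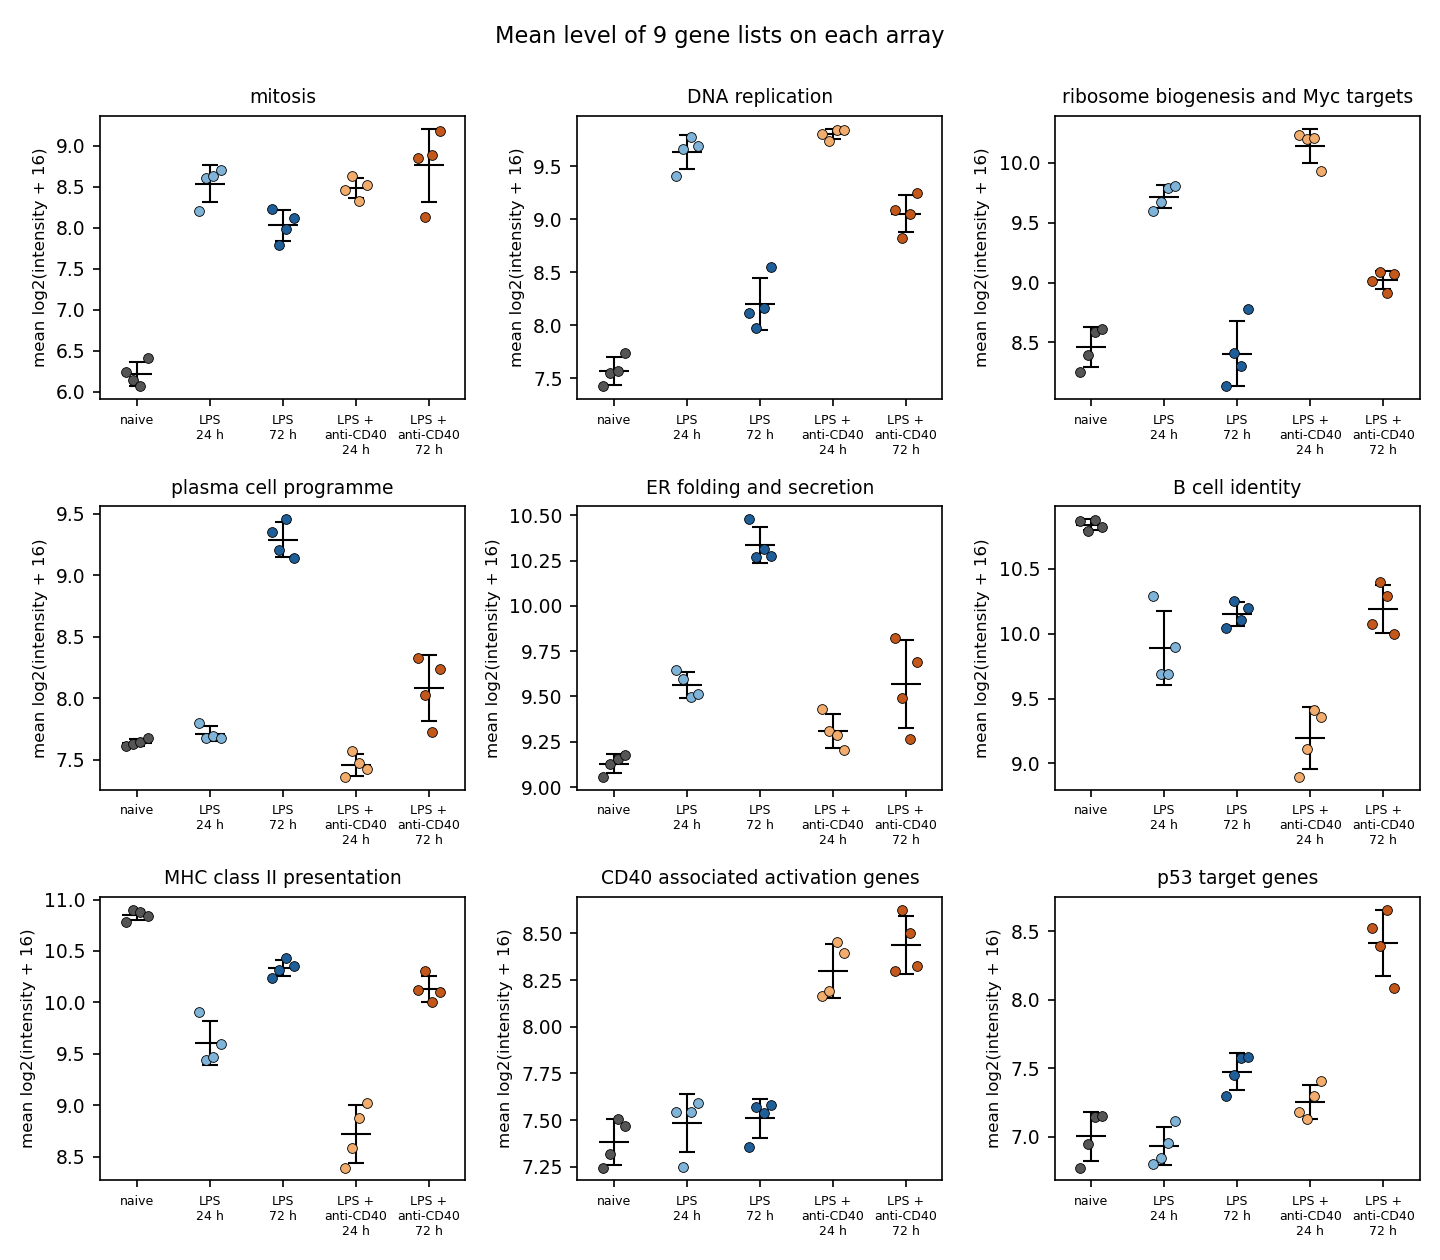
Mean log2(intensity + 16) of 9 fixed gene lists (y axis, log2 units) in the 5 groups (x axis), with 1 point per array and bars for the group mean ± SD (n = 4). The plasma cell programme averages 7.64 in naive cells, 9.29 with LPS and 8.08 with LPS plus anti-CD40 at 72 h, and MHC class II presentation falls from 10.85 in naive cells to 9.6 and 8.72 at 24 h without and with anti-CD40.

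By number set, the change of LPS cultures between 24 h and 72 h held 2647 genes among the other arrays and 1216 among the pair of arrays numbered 6, and centring on array medians moved its split to 867 higher and 1547 lower. Mitosis genes averaged 8.53 at 24 h and 8.03 at 72 h against 6.21 in naive cells, and DNA replication genes 9.63 and 8.2 against 7.57. Between 24 h and 72 h mitosis genes fell in 11 of 29 and rose in 1, with 12 and 1 adjusted over the list alone (median -0.51, adjusted p = 0.00037), a call that had adjusted p = 0.47 with an estimated correlation. Mki67, a marker of cycling cells, stood at 0.16 ± 0.25 (adjusted p = 0.71) between the times.

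LPS plus anti-CD40 was compared with naive cells to see which genes differed after culture with the joint stimulus. At 24 h 5149 genes changed, 2766 higher and 2383 lower, 1439 and 1190 of them at least 2-fold. The chemokine gene Ccl22 rose by 6.55 ± 0.3 (adjusted p = 7.6e-14) and Il6 by 5.17 ± 0.29, sizes that the pseudocount sets in part, since both were dim in naive cells (4.62 and 4.18), while S1pr1 (-4.42 ± 0.2) and the ubiquitin ligase gene Marchf1 (-4.94 ± 0.24, to a dim level) fell. At 72 h 3326 genes changed, 1889 higher and 1437 lower, 890 and 500 of them at least 2-fold. Ccl22 was then higher by 6.69 ± 0.3 (adjusted p = 9.8e-14), the chemokine gene Ccl5 higher by 5.93 ± 0.32, Cdkn1a, the cell cycle inhibitor downstream of p53, higher by 4.22 ± 0.34, all from dim levels, and Prdm1 higher by 1.55 ± 0.29. At 24 h MHC class II genes fell in 13 of 16, 13 adjusted over the list alone (median -2.34, adjusted p = 5.1e-12), with H2-Ob at -4.33 ± 0.23, and BCR signalling genes in 24 of 26 (median -1.31, adjusted p = 3.5e-14), with Cd79a, a chain of the receptor's signalling dimer, at -3.16 ± 0.4. At 72 h mitosis genes rose in 28 of 29, 29 adjusted over the list alone (median 2.68, adjusted p = 6.6e-35), and DNA replication genes in 25 of 30 with 1 down, the same counts adjusted over the list alone (median 1.58, adjusted p = 3.4e-18). The plasma cell programme rose in 7 of 17 genes, 8 adjusted over the list alone (median 0.51, adjusted p = 0.014), with adjusted p = 0.14 with an estimated correlation and 0.072 among arrays numbered 6, 7 or 6A alone. At 24 h the split was 3087 higher and 1752 lower after centring on array medians, which moved all genes by a median of 0.11, and 2408 higher and 3071 lower with the deposited values, which moved them by -0.2. Within number sets, 3789 genes at 24 h and 1929 at 72 h passed among the other arrays, and 4730 and 3132 among arrays numbered 6, 7 or 6A.

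Adding anti-CD40 to LPS for 24 h asked what the CD40 signal changes early. Relative to LPS alone 713 genes differed, 319 higher and 394 lower, 109 and 158 of them at least 2-fold. These groups shared only replicate number 6, so the effect of anti-CD40 cannot be told apart from a difference between the other numbered samples. Without LPS replicate 1 the count was 417, and with only the groups compared in the fit it was 340. Ccl22 rose 19.4-fold (4.28 ± 0.3, adjusted p = 3.9e-09), the interleukin subunit gene Ebi3 5.46-fold (2.45 ± 0.22), Il6 3.65-fold (1.87 ± 0.29) and the death receptor gene Fas by 1.99 ± 0.24. The actin bundling gene Fscn1, dim with LPS alone, rose by 3.26 ± 0.32, though by 1.02 and not past the test with a pseudocount of 1. In that setting the probe set of each gene was chosen anew, so these values may belong to different probe sets. Among the genes that fell were Fcrla, an Fc receptor-like protein of B cells (6.53-fold lower, -2.71 ± 0.27), the quiescence factor Klf2 (-2.09 ± 0.31), Il10 (3.91-fold lower, -1.97 ± 0.36) and Prdm1 (2.39-fold lower, -1.26 ± 0.29, adjusted p = 0.0098). Centring on array medians moved all genes by a median of 0.24 and gave 1586 higher and 174 lower, and the deposited values moved them by -0.14 and gave 452 higher and 692 lower. Within number sets, 510 genes passed among the other arrays and 116 among arrays numbered 6 or 7.

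By list, CD40 associated activation genes rose at 24 h in 11 of 24, 13 adjusted over the list alone (median 0.49, adjusted p = 1.4e-10). MHC class II genes fell further than with LPS alone in 9 of 16, 12 adjusted over the list alone (median -0.83, adjusted p = 6.3e-13), among them H2-Ob (-1.96 ± 0.23), H2-Eb1 (-1.74 ± 0.24) and H2-Ab1 (-1.44 ± 0.25). BCR signalling genes fell in 11 of 26, with 18 down and 1 up adjusted over the list alone (median -0.61, adjusted p = 3.9e-13), with the inhibitory receptor Fcgr2b at -1.5 ± 0.16 and the phosphatase gene Ptpn22 at -1.59 ± 0.22. B cell identity genes fell in 12 of 24, with 17 down and 2 up adjusted over the list alone (median -0.76, adjusted p = 4.8e-13). NF-kB target genes rose in 8 of 21 and fell in 1, with 9 and 1 adjusted over the list alone (adjusted p = 1.3e-06), Tnfaip3 rising by 1.29 ± 0.25, with adjusted p = 0.099 with an estimated correlation. The stress arm of the unfolded protein response (UPR) rose in 5 of 15 genes and fell in 1, with the same counts adjusted over the list alone (median 0.71, adjusted p = 0.00021), including Chac1 (1.75 ± 0.23) and Trib3 (1.67 ± 0.27), with adjusted p = 0.13 with an estimated correlation. Ribosome biogenesis genes rose in 5 of 34, 13 adjusted over the list alone (median 0.44, adjusted p = 2.3e-09), with adjusted p = 0.099 with an estimated correlation. Plasma cell genes fell in 4 of 17, with 5 down and 1 up adjusted over the list alone (adjusted p = 0.019), with adjusted p = 0.17 with an estimated correlation, 0.13 with the deposited values and 0.12 with arrays centred on their medians. Mitosis genes were not past the test (adjusted p = 0.42, 1 down and 28 not past), though they were lower and past it without LPS replicate 1 (adjusted p = 0.035). The lists past the test numbered 21 of 32, and 5 with an estimated correlation.

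The same contrast at 72 h asked what anti-CD40 changes as plasma cell genes rise. Relative to LPS alone 1958 genes differed, 1176 higher and 782 lower, 389 and 247 of them at least 2-fold. These groups shared no replicate number, so the effect of anti-CD40 cannot be told apart from a difference between the numbered samples. Ccl22 rose 45.2-fold (5.5 ± 0.3, adjusted p = 1.6e-11), Ccl5 19.7-fold (4.3 ± 0.32), Il6 6.98-fold (2.8 ± 0.29) and Nfkb2, a subunit of the noncanonical NF-kB pathway, by 2.31 ± 0.23. Wfdc17 was lower (-4.76 ± 0.29) and dim with anti-CD40. Jchain was lower by a difference of -3.15 ± 0.5 (-2.46 without LPS plus anti-CD40 replicate 7), and Prdm1 was 6.14-fold lower (-2.62 ± 0.29, adjusted p = 1.5e-06). Il10 was 5.71-fold lower (-2.51 ± 0.36) and Xbp1 2.57-fold lower (-1.36 ± 0.17). The syndecan gene Sdc1, whose protein marks plasma cells, stood at 0.02 ± 0.27 (adjusted p = 0.98), and the activation factor Irf4 at -0.32 ± 0.23 (adjusted p = 0.38). Sdc1 had not risen with LPS alone at 72 h (5.72 to 6.25, against 6.18 to 6.76 in naive cells), so a loss could hardly show. Centring on array medians moved all genes by a median of 0.23 and gave 1764 higher and 266 lower. Within number sets, 985 genes passed among the other arrays and 821 among arrays numbered 6, 7 or 6A.

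**Figure D3:**
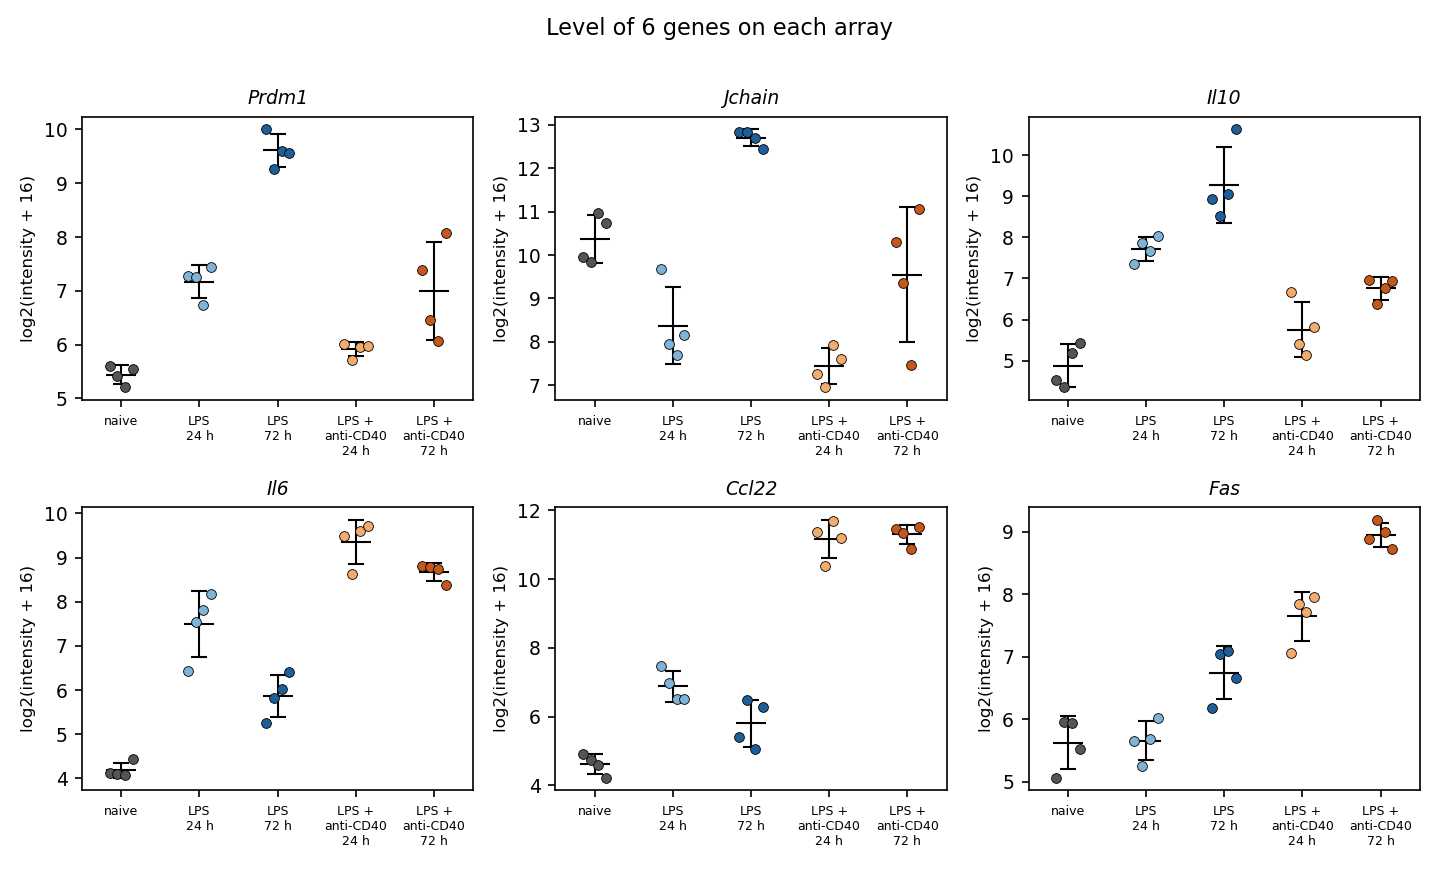
Level of 6 genes as log2(intensity + 16) (y axis, log2 units) in the 5 groups (x axis), with 1 point per array and bars for the group mean ± SD (n = 4). Prdm1 differs by -2.62 and Ccl22 by 5.5 between LPS plus anti-CD40 and LPS at 72 h.

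At 72 h the plasma cell programme was lower with anti-CD40 in 11 of 17 genes, 12 adjusted over the list alone (median -1.36, adjusted p = 2.4e-13), with Fkbp11 at -2.26 ± 0.17 and Edem1 at -1.69 ± 0.15. ER folding and secretion genes fell in 24 of 37, 29 adjusted over the list alone (median -0.72, adjusted p = 5.1e-17), with Creld2 at -1.71 ± 0.3 and Sec24d at -1.67 ± 0.23. DNA replication genes rose in 20 of 30, 23 adjusted over the list alone (median 0.87, adjusted p = 3.3e-14), among them the thymidylate synthase gene Tyms (1.76 ± 0.26, dim with LPS alone) and Mcm3 (1.44 ± 0.19). The p53 target genes rose in 12 of 19 and fell in 1, with 12 and 2 adjusted over the list alone (median 0.78, adjusted p = 3.3e-07), including Phlda3 (2.73 ± 0.28), Cdkn1a (2.27 ± 0.34) and Fas (2.2 ± 0.24), against Trp53inp1 at -1.23 ± 0.21. CD40 associated activation genes rose in 13 of 24, with 16 up and 1 down adjusted over the list alone (median 0.61, adjusted p = 6.2e-08). Class switching genes rose in 8 of 24, 10 adjusted over the list alone (median 0.32, adjusted p = 0.00061), with an adjusted p of 0.051 among arrays numbered 6, 7 or 6A alone. That list was tested without Aicda and holds general DNA repair genes such as Parp1 and Rad50, so its rise need not concern class switching. Mitosis genes rose in 17 of 29, 22 adjusted over the list alone (median 0.73, adjusted p = 7.6e-11), with adjusted p = 0.15 with an estimated correlation. NF-kB target genes rose in 9 of 21, 11 adjusted over the list alone (adjusted p = 9.1e-06), with adjusted p = 0.14 with an estimated correlation. B cell identity genes were not past the test (adjusted p = 0.52, 3 up, 4 down and 17 not past), with a median of -0.12 and a mean of 0.04. The lists past the test numbered 17 of 32, and 7 with an estimated correlation.

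The difference made by anti-CD40 at 24 h and at 72 h, which shares no array between the times, correlated across genes with Pearson 0.46 and Spearman 0.43, and genes are not independent replicates. Both times called 297 genes, of which 287 moved the same way, 129 higher and 158 lower, where independent lists would share 30.4 and 25. The change between 24 h and 72 h in the arms with and without anti-CD40 correlated across genes with Pearson 0.66 and Spearman 0.6. Both arms called 1857 genes, 1835 of them moving the same way, with 869 higher and 966 lower at 72 h against 211 and 214 for independent lists. Values for independent lists leave out the deviations that same-numbered arrays shared between groups, so chance agreement can lie above them, by an amount that was not estimated.

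**Figure D4:**
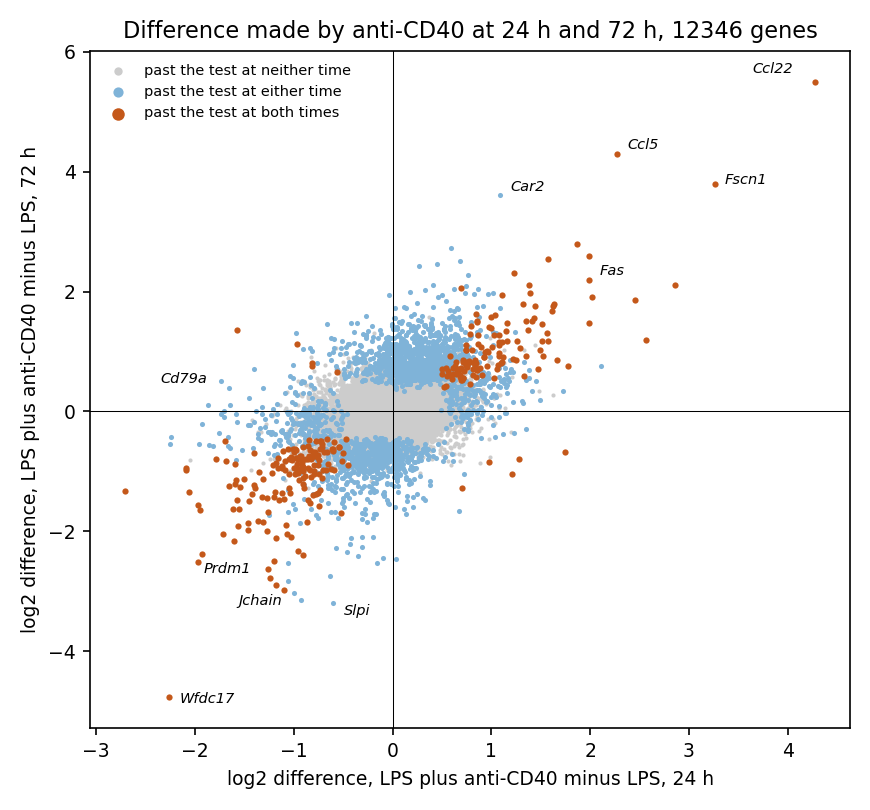
Log2 difference between LPS plus anti-CD40 and LPS alone at 24 h (x axis) and at 72 h (y axis), 1 point per gene for 12346 genes, coloured by whether the gene passed the test at neither, either or both times. Ccl22 lies farthest up at 4.28 and 5.5, and Wfdc17 farthest down at -2.26 and -4.76.

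Between 24 h and 72 h of LPS plus anti-CD40, a comparison of how the joint response moved on, 3177 genes changed, 1620 higher and 1557 lower, 668 and 422 of them at least 2-fold. H2-Ob, a modulator of class II loading, rose by 3.21 ± 0.23, Trp53inp1 by 3.44 ± 0.21 and Cd79a by 2.66 ± 0.4, while Cxcl10 (-2.84 ± 0.27) and Ifit1 (-1.99 ± 0.23) fell. The interferon response list was not past the test (adjusted p = 0.54, 5 up, 3 down and 20 not past). MHC class II genes rose in 14 of 16, 14 adjusted over the list alone (median 1.2, adjusted p = 2.3e-12), B cell identity genes in 17 of 24, with 17 up and 1 down adjusted over the list alone (median 0.75, adjusted p = 1.2e-10), and p53 target genes in 11 of 19, 12 adjusted over the list alone (median 0.82, adjusted p = 1.5e-08). Ribosome biogenesis genes fell in 32 of 34, 33 adjusted over the list alone (median -1.08, adjusted p = 1.4e-22). DNA replication genes fell in 20 of 30, 23 adjusted over the list alone (median -0.73, adjusted p = 5.4e-11), with adjusted p = 0.052 with an estimated correlation. The plasma cell programme rose in 9 of 17, 9 adjusted over the list alone (median 0.55, adjusted p = 0.00099), with adjusted p = 0.07 with an estimated correlation. Centring on array medians gave 1072 higher and 1876 lower, and the deposited values moved all genes by a median of 0.17 and gave 2122 higher and 1470 lower. Within number sets, 1519 genes passed among the other arrays and 2920 among arrays numbered 6, 7 or 6A. Of the 32 lists 18 passed, and 9 with an estimated correlation.

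Whether the effect of anti-CD40 itself differed between 24 h and 72 h was tested as an interaction, which 267 genes passed, 165 with a higher and 102 with a lower effect at 72 h. The transcription cofactor gene Lbh had an interaction of 2.95 ± 0.5 (adjusted p = 0.0031) and the carbonic anhydrase Car2 of 2.52 ± 0.47, against Slpi at -2.58 ± 0.4 (adjusted p = 0.0012) and the glutathione-degrading enzyme gene Chac1 at -2.42 ± 0.32 (adjusted p = 0.00042). The plasma cell programme as a list was lowered more at 72 h than at 24 h (median -0.99, adjusted p = 2.1e-10), with 4 of 17 genes lower, and 11 lower and 1 higher adjusted over the list alone, Cd28 standing at -1.81 ± 0.35. With LPS alone this list averaged 7.71 at 24 h and 9.29 at 72 h, against 7.64 in naive cells. At 24 h there was thus little rise to lower. BCR signalling genes had a higher effect at 72 h (5 of 26 up, 12 adjusted over the list alone, adjusted p = 4.3e-08), with adjusted p = 0.068 with an estimated correlation. Among the p53 target genes 3 of 19 were higher, 7 adjusted over the list alone (adjusted p = 5.7e-05), with Phlda3 at 2.14 ± 0.39 and Zmat3 at 1.62 ± 0.31, and the list had adjusted p = 0.068 with an estimated correlation. Prdm1 (-1.36 ± 0.41, adjusted p = 0.085), Il10 (-0.55 ± 0.5, adjusted p = 0.67) and Ccl22 (1.22 ± 0.42, adjusted p = 0.14) were not past the test, so their effects at the 24 h and 72 h points were not shown to differ, although Prdm1 passed without LPS plus anti-CD40 72 h replicate 45 (-1.72). Centring on array medians left 57 genes, split 28 and 29, and the deposited values gave 163 higher and 62 lower. Array weights gave 535 genes, a random replicate block 555 and the number sets as a block 450. Within number sets 3 genes passed among the other arrays and 41 among arrays numbered 6, 7 or 6A, and the count was 175 without LPS plus anti-CD40 24 h replicate 4, 141 and 138 without LPS 72 h replicates 1 and 3, and 145 without LPS plus anti-CD40 72 h replicate 7. Of the 32 lists 11 passed, and the plasma cell programme alone (1 list) with an estimated correlation.

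Markers of cell types other than B cells were read as list means over the members that passed the intensity filter. Members too dim to be tested do not enter these means. Neutrophil markers averaged 4.94 in naive cells and between 4.88 and 5.1 in the cultures, macrophage and monocyte markers 5.73 and between 5.41 (LPS plus anti-CD40 at 24 h) and 6.02 (LPS at 72 h), and T cell markers 6.12 and 5.4 to 6.39. The NK cell list, of which Ccl5 is a member, averaged 5.03 in naive cells and 6.47 with LPS plus anti-CD40 at 72 h, and the dendritic cell list 5.98 and 6.91, with its member Flt3 higher by 4.1 ± 0.24. With LPS alone at 72 h the NK cell list averaged 5.4 and the dendritic cell list 6.61. The ratio of the 5' to the 3' Gapdh probe set, a sign of RNA integrity, was 0.0798 on replicate 5 of LPS plus anti-CD40 at 24 h and lay between 1.06 and 1.25 on the other arrays of that group. The same ratio for actin was 0.425 on that array, 0.594 on replicate 4 of its group, and 0.606 and 0.601 on replicates 44 and 45 of LPS plus anti-CD40 at 72 h, and lay between 0.673 and 0.902 on all other arrays.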

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

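Of the tests in this part, the splits of the arrays and the test of p53 target genes found in no other list were chosen before their results were seen, and the other tests of patterns only after.

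Other splits of the arrays were counted for each comparison. With LPS at 24 h against naive cells, 1 of 35 splits of the 8 arrays, the real one, gave as many genes as the 4525 it gave when fitted alone, and the highest other split gave 0. The real split was likewise the only 1 of 35 for LPS at 72 h against naive cells (2897 genes, highest other 0), for LPS at 72 h against 24 h (2803 and 0), and for LPS plus anti-CD40 against naive cells at 24 h (5273 and 0) and 72 h (3997 and 0). It was also the only 1 for LPS plus anti-CD40 against LPS at 24 h (340 and 1) and 72 h (1659 and 0) and for LPS plus anti-CD40 at 72 h against 24 h (2999 and 0). For the interaction, 1 of 100 regroupings, the real one, reached 160 genes, and the highest other gave 1. No other split thus came near the count of the real one. For pairs of groups this follows from any large difference between them, since the other splits mix both groups and widen the spread. The counts thus do not tell a stimulus from a technical difference, and 1 of 35 is the lowest share they can reach. For LPS at 24 h and at 72 h against naive cells, whose 3 shared numbers pair arrays, the other splits that part as many pairs gave at most 0 genes.

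A lower level of B cell identity, MHC class II and BCR signalling genes with anti-CD40 at 24 h was weighed against technical sources, as replicate 5 of that group had a low 5' to 3' Gapdh ratio and replicates 4 and 5 had low actin ratios. Over the 58 genes the mean difference was -0.69 ± 0.15. Without replicate 5 it was -0.67 ± 0.18, and without replicates 4 and 5 it was -0.53 ± 0.17. This argues against the RNA of these replicates as the whole source, although a pair of arrays, 6 and 7, of 1 number set, was left. With the deposited values the mean difference was -0.54 ± 0.19 relative to the other tested genes, against -0.68 ± 0.16 after quantile normalization. With the number sets as a block it was -0.73 ± 0.15. In that block the other numbers were replicates 1, 2 and 3 with LPS but 4 and 5 with anti-CD40. The block cannot remove a difference between those samples. Macrophage and monocyte markers and stromal markers were lower as lists as well (adjusted p = 0.023 and 0.046), but had adjusted p = 0.14 and 0.18 with an estimated correlation. Whether joint stimulation itself lowered these B cell genes stays a hypothesis, because the pattern was found and tested on the same arrays.

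A lower level of plasma cell and ER genes with anti-CD40 at 72 h was the second pattern (-0.91 ± 0.13 over 54 genes). From LPS to LPS plus anti-CD40 at 72 h, mean T cell markers also went from 6.39 to 5.6 and NK cell markers from 5.4 to 6.47. The NK cell list holds Ccl5, which rose between these groups, so its mean need not reflect NK cells. With the number sets as a block the difference over the 54 genes was -0.84 ± 0.1. Relative to the other genes it was -0.86 ± 0.17 with the deposited values, against -0.94 ± 0.13 after quantile normalization. These values argue against scaling, and against the split of 6, 7 and 6A from the other numbers, as the whole source. In that block the other numbers were replicates 1, 2 and 3 with LPS but 44 and 45 with anti-CD40. The block cannot remove a difference between those samples. Without replicates 44 and 45, whose actin ratios were low, the difference over the 54 genes was -1.1 ± 0.11. That left 6A and 7, of 1 number set, against LPS arrays mostly of the other set. The Gapdh ratio at 72 h was 1.11 to 1.25 with anti-CD40 and 1.29 to 1.62 with LPS. A part of RNA quality in the pattern thus cannot be excluded. A smaller share of plasma-like cells, with no change within cells, and a lower level within cells cannot be told apart. Of 91 pairs of genes 37 differed by over 2 SE in the share of the rise that was kept (median 13.9% over 14 genes), but the other cells of a culture need not stay at naive levels, and no array measured the cells apart.

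A higher level of p53 target genes with anti-CD40 at 72 h was the third pattern (0.94 ± 0.14 over 19 genes). Genes shared with other lists were not its source, since the 14 genes found in no other list differed by 0.87 ± 0.14. With the number sets as a block the difference was 0.89 ± 0.13, and without replicates 44 and 45, whose actin ratios were low, 1.05 ± 0.13. The arrays then left with anti-CD40 were of 1 number set, and Gapdh ratios did not overlap between these groups. A part of RNA quality thus cannot be excluded, nor can a difference between the numbered samples, since these groups shared no replicate number. A response of p53 to the joint stimulation may lie behind the higher level, and stays a hypothesis, since p53 activity was not analysed here.

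The effect of anti-CD40 differed between 24 h and 72 h, by the test of the interaction, for the following named genes, given as the log2 effect at 72 h minus that at 24 h. It was higher at 72 h for Lbh (2.95), Car2 (2.52), Arhgef1 (2.29), Cd79a (2.25), Phlda3 (2.14), Cd37 (2.1), Ccl5 (2.03), Adgre1 (1.85), Tgfb1 (1.81), H2-Eb1 (1.69), Blk (1.63), Zmat3 (1.62) and Pold1 (1.59). Smaller differences of this sign were those of Bak1 (1.47), Bcl3 (1.44), Aurka (1.43), H2-Ob (1.42), Cad (1.42), Spib (1.41), H2-DMb2 (1.41), Ube2c (1.39), Lig1 (1.38), Bbc3 (1.36), Plk1 (1.35) and Ptpn6 (1.32). The same sign was found for H2ax (1.21), Ccnb2 (1.2), Mcm2 (1.16), Cd22 (1.16), Mcm3 (1.12) and Ndufab1 (0.85). It was lower at 72 h for Slpi (-2.58), Wfdc17 (-2.5), Evi5 (-2.49), Chac1 (-2.42), Fkbp11 (-1.95), Cd28 (-1.81), Slc2a1 (-1.43), Herpud1 (-1.21), Klf3 (-1.19), Edem1 (-1.17), Tram2 (-1.15), Slc3a2 (-1.01), Sod2 (-0.99), Rpn1 (-0.98) and Spcs1 (-0.74).

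Most of these 46 calls depended on the settings. With the deposited values 9 ended, those of Tram2, Ccnb2, Mcm3, Rpn1, Spcs1, Ndufab1, Cad, Bbc3 and Cd22, with arrays centred on their medians 33 ended, and with the mean of probe sets 18 of 45 ended or turned, Ndufab1 to -0.27. With a pseudocount of 1, 10 ended, among them that of Wfdc17, and leaving out 1 array ended between 2 and 17. Within number sets 2 of the 46 held among the other arrays and 7 among arrays numbered 6, 7 or 6A. Apart from the comparisons within number sets, 10 held in every setting, those of Lbh, Car2, Arhgef1, Phlda3, Blk, Zmat3, Slpi, Evi5, Chac1 and Cd28.

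Mean effects of whole lists also differed between the times (anti-CD40 by time interaction). They were higher at 72 h for mitosis (0.78), B cell identity (0.74), DNA replication (0.68), MHC class II presentation (0.68), p53 target genes (0.61), BCR signalling (0.6) and the Bcl-2 family (0.36), and lower for the plasma cell programme (-0.96), the stress arm of the unfolded protein response (-0.56), ER folding and secretion (-0.51) and the interferon response (-0.35). Of these 11 lists, the plasma cell programme alone was past the test with an estimated correlation. The interferon call had an adjusted p of 0.061 without LPS 24 h replicate 1, and of 0.09 and 0.07 without LPS plus anti-CD40 24 h replicate 6 and 72 h replicate 7. For the Bcl-2 family the adjusted p was 0.068 without LPS 24 h replicate 2, 0.068 without LPS plus anti-CD40 24 h replicate 4, 0.095 and 0.051 without LPS 72 h replicates 1 and 6, and 0.07 without LPS plus anti-CD40 72 h replicate 7, and it was 0.052 with no filter and 0.071 with arrays centred on their medians. Among arrays numbered 6, 7 or 6A the adjusted p was 0.68 for the interferon response and 0.21 for the Bcl-2 family, and among the other arrays 0.13 for the stress arm.

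Single arrays lay far from the other 3 of their group in 14 of 270 groups tested, where chance gives about 1 in 20. Among genes, Sdc1 was 6.49 on LPS 24 h replicate 3 (others 5.55 to 5.65), Bcl6 8.24 on LPS 24 h replicate 1 (7.14 to 7.28), and Il6 4.43 on naive replicate 7 (4.08 to 4.12) and 8.38 on LPS plus anti-CD40 72 h replicate 45 (8.74 to 8.8). Among list means, the plasma cell programme was 7.8 on LPS 24 h replicate 1, CD40 associated activation genes 7.25 on LPS 24 h replicate 2, glycolysis 9.45 on LPS 72 h replicate 6 and stromal markers 5.2 on naive replicate 6. With LPS plus anti-CD40, ribosome biogenesis was 9.93 on 24 h replicate 7, and at 72 h MHC class I presentation was 10.49 on replicate 6A, oxidative phosphorylation 10.48 on replicate 45 and T cell markers 5.88 on replicate 44. The 5' to 3' Gapdh ratio was 1.41 on LPS 24 h replicate 1 (others 1.24 to 1.26) and 0.0798 on LPS plus anti-CD40 24 h replicate 5 (1.06 to 1.25).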

How the results depend on the processing

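Alternatives by number set, and centring on medians for the list tests, were added after the data were seen, and the others were planned. Counts of changed genes kept within 1.5-fold of the reported count under the pseudocounts, filters, mean of probe sets and robust shrinkage. Testing all probe sets gave 7995 and 4913 for LPS at 24 h and 72 h against naive cells, 5292 between the times, 9395 and 5581 for LPS plus anti-CD40 at 24 h and 72 h against naive cells and 4818 between these times, as more features were tested. An adjusted p of 0.01 left 1799 genes for LPS at 72 h against naive cells, 2191 for LPS between times, 299 and 936 for the effect of anti-CD40 at 24 h and 72 h, 1958 for LPS plus anti-CD40 between times and 61 for the interaction, by its construction. The effect of anti-CD40 at 24 h moved to 1144 genes with the deposited values, 1760 with arrays centred on their medians and 340 with only its groups fitted, and that at 72 h to 3335 with array weights. The interaction moved to 57 with arrays centred on their medians, 160 with only its groups, 535 with array weights, 555 with a random replicate block and 450 with the number sets as a block. The cause was not tested.

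Within number sets fewer arrays were compared, and a lone array was assumed to vary like the other groups. Arrays numbered 6, 7 or 6A gave 2854 for LPS at 24 h against naive cells, 1216 for LPS between times, 116 and 821 for anti-CD40 at 24 h and 72 h and 41 for the interaction. The other arrays gave 1377 for LPS and 1929 for LPS plus anti-CD40 at 72 h against naive cells, 985 for anti-CD40 at 72 h, 1519 for LPS plus anti-CD40 between times and 3 for the interaction. The block by replicate number, fitted only on the arrays of shared numbers in the groups compared, gave 4858 and 2568 for LPS at 24 h and 72 h against naive cells, 3576 for LPS between times and 5998 for LPS plus anti-CD40 at 24 h against naive cells. Among named genes it kept 462 of 479 calls and added 8, and among lists it kept all 67 and added 2.

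With an estimated correlation the lists past the test were 6 for LPS at 72 h against naive cells and 7 between times, 11 and 9 for LPS plus anti-CD40 at 24 h and 72 h against naive cells, 5 and 7 for anti-CD40 at 24 h and 72 h, 9 for LPS plus anti-CD40 between times and 1 for the interaction. Of 158 list calls this kept 66 and ended 92, while the deposited values kept 146 and centring on medians 145. Of 960 named gene calls the deposited values kept 906 and ended 54, and centring kept 816 and ended 143. Over genes past either test, the correlations across genes were 0.586 for anti-CD40 at both times and 0.75 for time in both arms. The interferon response between the times of LPS turned from higher to lower among arrays numbered 6, 7 or 6A (adjusted p = 0.94). Reversed values of genes were those of Spcs2 for anti-CD40 at 24 h (0.07 with arrays centred on their medians), and, with the mean of probe sets, of H2-D1 for LPS at 24 h against naive cells (0.21) and of Ndufab1 for the interaction (-0.27).

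Leaving out 1 array gave 3736 to 4252 and 2291 to 2900 for LPS at 24 h and 72 h against naive cells, 2789 to 3269 between times, 4623 to 5011 and 2828 to 3084 for LPS plus anti-CD40 at 24 h and 72 h against naive cells and 2512 to 3097 between times. It gave 417 to 772 and 1325 to 2257 for anti-CD40 at 24 h and 72 h, and 138 to 339 for the interaction. Over these fits 1293 of 1352 list calls were kept and 59 ended, and 22 were added. The correlations ran from 0.385 to 0.494 and from 0.624 to 0.687. With up to 56.2% of an array's values below the pseudocount, differences of dim genes are compressed, and their signal over background limits what could be called.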

Other observations

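Oxidative phosphorylation genes rose with LPS at 24 h in 22 of 37, with 1 down, and in 24 with 1 down adjusted over the list alone (median 0.48, adjusted p = 1.4e-06, and 0.048 with an estimated correlation), the electron carrier Cycs rising by 1.26 ± 0.18. Immunoglobulin transcripts rose between 24 h and 72 h of LPS in 5 of 6, 5 adjusted over the list alone (median 1.33, adjusted p = 0.0013), with Igk at 2.59 ± 0.47 and Ighg3 at 2.53 ± 0.26, and had adjusted p = 0.13 with an estimated correlation. Cytokine and chemokine genes rose with anti-CD40 at 24 h in 8 of 22, with 1 down, and 9 and 2 adjusted over the list alone (median 0.22, adjusted p = 0.00072), with adjusted p = 0.099 with an estimated correlation and 0.13 among arrays numbered other than 6, 7 or 6A.

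Genes of cell death and of LPS sensing moved in both directions. Bcl-2 family genes were not past the list test for anti-CD40 at 72 h (adjusted p = 0.17, 3 up, 2 down and 10 not past, and 8 up and 2 down adjusted over the list alone), where the proapoptotic members Bcl2l11 (-1.45 ± 0.24) and Bbc3 (1.41 ± 0.26) moved apart. Genes of TLR signalling and LPS sensing fell with LPS at 24 h in 6 of 23, with 1 up and the same counts adjusted over the list alone (median -0.33, adjusted p = 0.011), Tlr1 standing at -1.44 ± 0.19, and had adjusted p = 0.13 with an estimated correlation and 0.073 among arrays numbered other than 6, 7 or 6A. MHC class I genes were not past the test at that time (adjusted p = 0.51, 2 up, 4 down and 7 not past).

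Lists of other cell types were not past the test for LPS at 24 h against naive cells. T cell markers had an adjusted p of 0.68 (1 up, 1 down and 4 not past, median 0.1, mean and test lower), NK cell markers of 0.86 (1 up, 1 down and 2 not past), macrophage and monocyte markers of 0.94 (1 up, 1 down and 10 not past) and neutrophil markers of 0.92 (0 of 5 past the test). Dendritic cell markers had an adjusted p of 0.82 (2 up, 1 down and 7 not past), erythroid and platelet markers of 0.66 (1 down and 9 not past, median 0.02, mean and test lower) and stromal markers of 0.94 (1 up, 1 down and 5 not past). With anti-CD40 at 24 h against LPS alone, macrophage and monocyte markers were lower as a list (median -0.33, adjusted p = 0.023) with 0 of 12 genes past the test, and stromal markers with 1 of 7 lower (median -0.36, adjusted p = 0.046), the counts being the same adjusted over each list alone. With an estimated correlation their adjusted p was 0.14 and 0.18, with no filter 0.13 and 0.16, and with the number sets as a block 0.054 and 0.086. The macrophage call had adjusted p = 0.061 without LPS replicate 2 and 0.06 without LPS plus anti-CD40 replicate 7, and the stromal call 0.054 and 0.11 without LPS replicates 1 and 2 and 0.079, 0.087 and 0.065 without LPS plus anti-CD40 replicates 5, 6 and 7. Dendritic cell markers were higher with LPS plus anti-CD40 at 72 h than in naive cells in 5 of 10 genes and lower in 1, also adjusted over the list alone (median 0.7, adjusted p = 0.042), with adjusted p = 0.078 with an estimated correlation, 0.068 with the deposited values and 0.11 with no filter. With anti-CD40 at 72 h, T cell markers fell in 2 of 6 genes against LPS alone, 3 adjusted over the list alone (median -0.63, adjusted p = 0.015), with Cd2 at -2.04 ± 0.27, but had adjusted p = 0.062 with an estimated correlation, 0.16 with no filter and 0.11 among arrays numbered 6, 7 or 6A.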
